A study of Mus musculus with 18 samples.

How the data were processed

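Polyadenylated RNA was measured in colon tissue of untreated C57BL/6 mice, with 9 libraries labelled as wild type for Hif2a (WT) and 9 labelled as carrying an altered Hif2a allele (HIF2). The labels describe the HIF2 mice as overexpressing HIF2 in the colon. The allele is written as LSL in the design text and as LFL in the sample labels, and its structure is not given in the sources used here. Libraries were prepared with the TruSeq RNA kit v2, per the labels' protocols. Tissue was fresh or frozen, and which library came from which is not given in the sources used here. The labels do not say that each library came from a separate mouse, so p-values measure the spread between these libraries.

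The deposited values were FPKM (fragments mapped to a gene, scaled by transcript length and library size), 1 column per library and 27131 rows. The submitters' processing notes name FastQC, Bowtie2 2.1.0.0, TopHat2 2.0.9, TopHat, Cuffdiff 2.1.1, Cufflinks and the mm10 build, without roles or order. Read depth, strand setting, counting parameters and annotation release are not given in the sources used here. The kit named does not mark strand, so overlapping and antisense genes cannot be told apart, and near-identical copies such as defensin and haemoglobin genes are uncertain. The FPKM columns summed to between 686539 and 937505, and their upper quartiles lay between 8.86 and 9.14. The 5 highest rows, Gm20594, Scarna2, Rpph1, Scarna10 and Rmrp, held between 26.7% and 36.5% of each sum. Absolute depth is unknown. From 4177 low genes, the most common ratio of a library's value to that in WT replicate 0 lay between 1 and 1.39, over genes above 0 in both. If that ratio compares 1 fragment with 1 fragment, which was not checked, relative depth differed little between libraries. No interval from counting error was computed.

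Values were analysed as log2(FPKM + 1), without further scaling. Fold changes on this scale understate the change of low genes. Genes with a mean FPKM of at least 1 over the 18 libraries were tested, 13976 in all. The main test was limma 3.58.1 in R 4.3.3, with a trended prior, 2-sided, and Benjamini-Hochberg adjustment at 0.05. All adjusted p-values of single genes are from limma. Data were simulated for this comparison with each gene drawn independently from a normal distribution and 200 of 13976 genes changed. On these the procedure recovered 91% of 2-fold and 99% of 4-fold changes, with 7 false calls. It made 0 calls when no gene was changed. Differences shared by many genes within a library were not simulated, so these rates need not hold for the real data.

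A set of 40 gene lists, 883 entries of which 857 matched a row, was fixed before the data were examined, as were the main test, the rule for named genes and the alternatives, apart from 2 subsets of libraries. Lists with at least 5 tested members, 37 in all, were tested with limma's camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry. The mean of each list per library was compared by an exact permutation test over 48620 splits, whose smallest possible p is 4.11e-05. Some genes belong to more than 1 list. Mast cell and eosinophil genes and sex-linked genes, with 4 tested members each, were not tested as lists, and none of the mitochondrially encoded genes matched a row.

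Named genes were Epas1, Hif1a, Arnt, Gt(ROSA)26Sor and Cxcl1. Also named were the 10 largest changes in each direction past the threshold, with at least 8 HIF2 libraries on that side of the WT median and leaving out predicted genes and small RNAs. From each list, up to 4 members in total were named, an even share from each direction by smallest p, with members that give a value without passing. Chemoattractant and neutrophil genes with a mean FPKM of at least 1 in either group completed the rule. Other names are said to have been chosen after their values were seen. Not every gene the rule takes is reported here. Coordinates are 1-based, from the GENCODE M21 annotation of GRCm38, the assembly that mm10 denotes.

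Alternatives covered pseudocounts of 0.1 and 0.01, a filter at a mean FPKM of 5 or none, 3 other scalings, the replicate number as a block, a robust prior, array weights, an exact rank test, covariates for sex-linked genes and for smooth muscle RNA, and each library left out. Figures were drawn with matplotlib 3.10.9. All 18 columns were used.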

Results

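Gene expression was compared between colon tissue from 9 WT and 9 HIF2 libraries, to ask which genes differ when HIF-2α, the hypoxia-inducible transcription factor encoded by Epas1, is overexpressed in the colon. The series title places the study in work on epithelial HIF-2α, colon tumours and neutrophil recruitment. Libraries were named by genotype and replicate number, 0 to 8 in each group. FPKM sums ranged from 686539 to 937505 per library. The highest correlation between any 2 libraries was 0.931, and none were treated as duplicates. The first principal component carried 22% of the variance and the second 11.2%, and on the second HIF2 replicates 6, 7 and 8 lay apart at -50.9, -58 and -52. The Y-linked gene Ddx3y was near 0 FPKM in WT replicates 5 to 8 and in HIF2 replicates 3, 6, 7 and 8. The labels give no sex.

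Epas1 (chromosome 17, 86753700 to 86833410) was 18.8 ± 3.09 FPKM in WT and 22.7 ± 6.36 in HIF2 (SD, n = 9 each). The difference of 0.24 on the log2 scale (SE 0.14) was not larger than the spread between replicates (exact permutation p = 0.116, limma adjusted p = 0.246). In HIF2 replicates 6 to 8 against 8 WT libraries, a subset chosen after the data were seen, it was 0.47 (limma adjusted p = 0.0415). Sex-linked genes were unbalanced there, with a median change of -2.17 over 4 genes, against 0.009 in the main test. The median was 1.37 in HIF2 replicates 0 to 5 and -2.13 with the smooth muscle covariate. These settings, used below, therefore do not isolate muscle RNA. For Epas1, 5 of the 9 HIF2 libraries lay inside the WT range of 13.8 to 23 FPKM. HIF2 replicate 0 was highest at 35.9 FPKM. Whether this row counts RNA of the transgene is not given in the sources used here. Hif1a, the related factor, differed by -0.30 (SE 0.18, adjusted p = 0.248), and without HIF2 replicate 0, where it was 142 FPKM, by -0.465 with an adjusted p of 0.00359, and it also passed with array weights (adjusted p = 0.0152). Arnt, the shared dimer partner, differed by -0.06 (SE 0.11, adjusted p = 0.755). Gt(ROSA)26Sor, a name shared by 2 rows, differed by -0.66 (SE 0.88, adjusted p = 0.655). Groups throughout are those of the labels.

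Between the groups, 1531 of 13976 genes were higher in HIF2 and 1557 were lower (limma, adjusted p under 0.05). Of these, 684 were higher and 208 lower by at least 2-fold. At an unadjusted p under 0.05 there were 4707 genes. The median log2 change over all genes was -0.02. Genes responding to HIF, smooth muscle, stromal and macrophage genes were among those higher in HIF2, and interferon response, absorptive and xenobiotic genes were among those lower. With the smooth muscle mean as a covariate the counts were 943 higher and 1000 lower, and with a filter at 5 FPKM 640 were higher, 33.8% of the calls against 49.6% in the main test.

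HIF target genes other than glycolytic ones rose in HIF2. Of 27 tested members, 16 rose and 1, the carbonic anhydrase gene Car12, fell, and adjusted over the list alone 18 rose and 1 fell. The list's camera adjusted p was 9.88e-10, and its adjusted p was 0.0761 with an estimated correlation. Slc11a2 (chromosome 15, 100387898 to 100425072), the intestinal iron importer, is outside this list. It rose from 15.4 ± 2.39 to 782 ± 850 FPKM (SD, n = 9 each), a log2 change of 4.24 (SE 0.81, adjusted p = 0.00118). Egln3, a prolyl hydroxylase that acts on HIF subunits (chromosome 12, 54178981 to 54203860), is in the HIF pathway list. It rose from 16.1 to 316 FPKM, by 3.56 (SE 0.60, adjusted p = 0.000485). Ankrd37 (chromosome 8, 45996902 to 46005707) rose from 14.3 to 245 FPKM, by 3.47 (SE 0.51, adjusted p = 0.000171). The metallothionein gene Mt1 rose by 1.46.

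Slc11a2 and Egln3 were not raised in every HIF2 library. Slc11a2 was 16.5 and 18.2 FPKM in HIF2 replicates 2 and 4, inside the WT range of 12.8 to 19 FPKM, and between 229 and 2101 FPKM in the other HIF2 libraries. Egln3 was 21.8 and 16.7 FPKM in those 2 libraries, against a WT maximum of 22.2 FPKM. Myl7, a myosin light chain gene outside the lists, rose by 4.03 and was 4.21 and 9.34 FPKM in those 2 libraries, against a WT maximum of 14.2 FPKM. The mean of the HIF target list, relative to the WT mean, was 0.61 and 0.28 there, above the WT maximum of 0.16. In the same 2 libraries the smooth muscle mean was 3.69 and 3.44 and the fibroblast mean 2.23 and 2.14. The HIF target list includes the matrix enzyme genes Lox and Loxl2, chosen after their values were seen, which rose by 1.87 and 2.05. The mean of the list differed by 1.08 between the groups (exact permutation p = 4.11e-05, the smallest these splits can give).

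**Figure D1:**
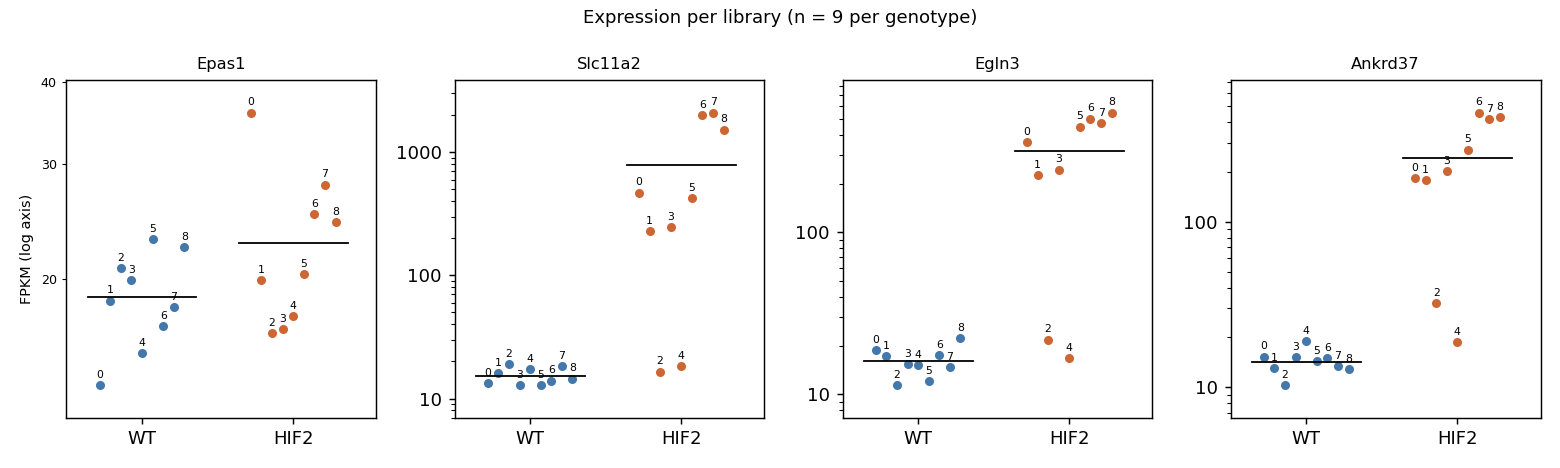
FPKM per library on a log axis for Epas1, Slc11a2, Egln3 and Ankrd37 in the 9 WT and 9 HIF2 libraries; points are libraries labelled with their replicate number and horizontal lines are group means. Slc11a2 was 16.5 and 18.2 FPKM in HIF2 replicates 2 and 4 and at least 229 FPKM in the other HIF2 libraries.

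Iron handling genes changed in both directions, with 7 of 23 higher and 4 lower, and adjusted over the list alone 7 and 5 (median 0.028, camera adjusted p = 0.229). The mean of the list differed by 0.64 (exact permutation adjusted p = 0.00137). In HIF2 replicates 6 to 8 against 8 WT libraries, a subset chosen after the data were seen, 11 rose and 5 fell (median 0.288, camera adjusted p = 0.0385). Steap4, a metalloreductase (chromosome 5, 7960457 to 7982213), rose from 4.74 ± 2.58 to 204 ± 177 FPKM, by 4.31 (SE 0.72, adjusted p = 0.000466). The transferrin gene Trf rose by 1.67 and the ceruloplasmin gene Cp by 1.65, whereas Steap3 fell by 0.58, a call lost with the smooth muscle covariate (adjusted p = 0.0526), and the metal transporter gene Slc39a8 fell by 0.41. Of 19 glycolytic genes, 4 rose and 2 fell, and adjusted over the list alone 7 and 3 (camera adjusted p = 0.058). The list passed without WT replicate 4 or any 1 of HIF2 replicates 1 to 4, with adjusted p down to 0.0111. It also passed with the filter at 5 FPKM, TPM scaling, quantile normalization and a replicate block (adjusted p = 0.016, 0.0104, 0.0144 and 0.0362). In the list, 11 rose and 2 fell with the smooth muscle covariate (adjusted p = 0.000133), and in HIF2 replicates 6 to 8 against 8 WT libraries 12 and 2 (adjusted p = 4.08e-06). In HIF2 replicates 0 to 5 against 9 WT libraries, likewise chosen after the data were seen, 1 rose and 3 fell (median 0.06, adjusted p = 0.607). Ldha, lactate dehydrogenase, rose by 0.72, a call lost in HIF2 replicates 0 to 5 (0.41, adjusted p = 0.0506), and Gapdh by 0.49, while Hk1 fell by 0.59 and Eno1 fell by 0.24, a call lost with quantile normalization (adjusted p = 0.0548). In the HIF pathway list, 3 of 10 rose and 0 fell, the same adjusted over the list alone (camera adjusted p = 0.154), among them Hif3a, by 1.72. The mean of that list differed by 0.48 (exact permutation adjusted p = 0.00609). Of 12 vessel growth factor genes, 2 rose, Angptl4 by 1.40 and Adm by 1.13, and 3 adjusted over the list alone (camera adjusted p = 0.0346, and adjusted p = 0.18 with an estimated correlation). That list call was lost without WT replicate 3, 4 or 6 (adjusted p up to 0.055), with quantile normalization, array weights or sex-linked genes as covariates (adjusted p = 0.0789, 0.0899 and 0.0548), and in HIF2 replicates 0 to 5 (adjusted p = 0.0827), and the call of Adm in the exact rank test (adjusted p = 0.0765) and in that subset (adjusted p = 0.0918). Nsg2, a neuronal vesicle gene (chromosome 11, 32000463 to 32059202), rose from 0.616 to 41.2 FPKM, by 4.26 (SE 0.46, adjusted p = 8.11e-06).

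Neutrophil recruitment genes showed few calls. Of 10 tested chemoattractant genes, 1 rose, the platelet factor gene Pf4 by 2.17 (SE 0.31, adjusted p = 0.000125), and 1 fell, Ccl6 by -1.60 (SE 0.28, adjusted p = 0.000702), with the same counts adjusted over the list alone (camera adjusted p = 0.238). Cxcl1 (chromosome 5, 90891241 to 90893115), a neutrophil chemoattractant, was 0.211 ± 0.283 FPKM in WT and 4.64 ± 12.4 in HIF2 (log2 difference 0.82, SE 0.52, exact permutation p = 0.0818, adjusted p = 0.299). It was 37.6 FPKM in HIF2 replicate 0. Cxcl2 differed by 0.54 (adjusted p = 0.568) and by -0.08 without that library, and Cxcl5 by 0.75 (adjusted p = 0.444). Without HIF2 replicate 0, Cxcl1 differed by 0.291 and Cxcl5 by 0.121. Of 7 neutrophil markers, 1 rose, Itgam by 1.82, an integrin gene also used by macrophages, and 1 adjusted over the list alone. The markers' camera adjusted p was 0.0586, and it was 0.0327, 0.0326 and 0.0446 without HIF2 replicates 1, 2 and 3, while the exact permutation test of their mean gave a difference of 0.91 and an adjusted p of 0.00215. Without HIF2 replicate 0 that difference was 0.49 (exact permutation p = 0.00181), with the same 7 of 26 listed markers. These include Itgam, and members such as Il1r2 that passed the filter only through HIF2 replicate 0. Il1r2 was 15.5 FPKM there, at most 1.22 in the other HIF2 libraries and 0.03 on average in WT. The markers were thus not chosen apart from that library, so this p does not show a neutrophil signal without it. Camera also passed with pseudocounts of 0.1 and 0.01, no filter and TPM scaling (adjusted p = 0.0302, 0.0216, 0.00778 and 0.037), with the smooth muscle covariate (adjusted p = 0.0348) and in HIF2 replicates 6 to 8 (adjusted p = 0.0207). Their mean relative to WT was 4.27 in HIF2 replicate 0 and between -0.06 and 1.11 in the other HIF2 libraries.

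Across the 18 libraries, Cxcl1 and the neutrophil marker mean had a Pearson r of 0.91 (permutation p = 0.011) and a Spearman rho of 0.437 (permutation p = 0.0713). Over the 15 relations computed, the adjusted values were 0.0615 and 0.392. Without the 2 libraries farthest in Cxcl1, r was 0.503, so the relation rested on them. Within WT, r was 0.365 (permutation p = 0.315) and within HIF2 0.918 (permutation p = 0.0787). None of the 15 relations, among Cxcl1, Epas1, HIF target, neutrophil and smooth muscle values, had an adjusted p under 0.05.

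Interferon response genes fell. Of 31 tested members, 29 fell and 0 rose, and adjusted over the list alone also 29 and 0, with a median log2 change of -1.52. The camera adjusted p was 1.48e-27, and the adjusted p was 0.101 with an estimated correlation. The mean of the list differed by -1.73 (exact permutation p = 4.11e-05, the smallest these splits can give). The antiviral gene Oas3 (chromosome 5, 120753098 to 120777661) was 31.5 ± 8.68 FPKM in WT and 3.44 ± 3.58 in HIF2, a log2 change of -3.10 (SE 0.29, adjusted p = 2.41e-06). Isg15 (chromosome 4, 156199424 to 156200818), a ubiquitin-like modifier, changed by -2.98 (SE 0.33, adjusted p = 9.48e-06). Oasl2 changed by -2.99 and Oas2 by -2.76, and Rsad2 by -2.08. Ddx60 and Apol9b, outside the list, changed by -2.85 and -2.61. The list mean lay below the WT range in each of the 9 HIF2 libraries, at -0.52 in HIF2 replicate 4, -1.29 in replicate 2 and between -1.55 and -2.54 in the others, against a WT minimum of -0.35.

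**Figure D2:**
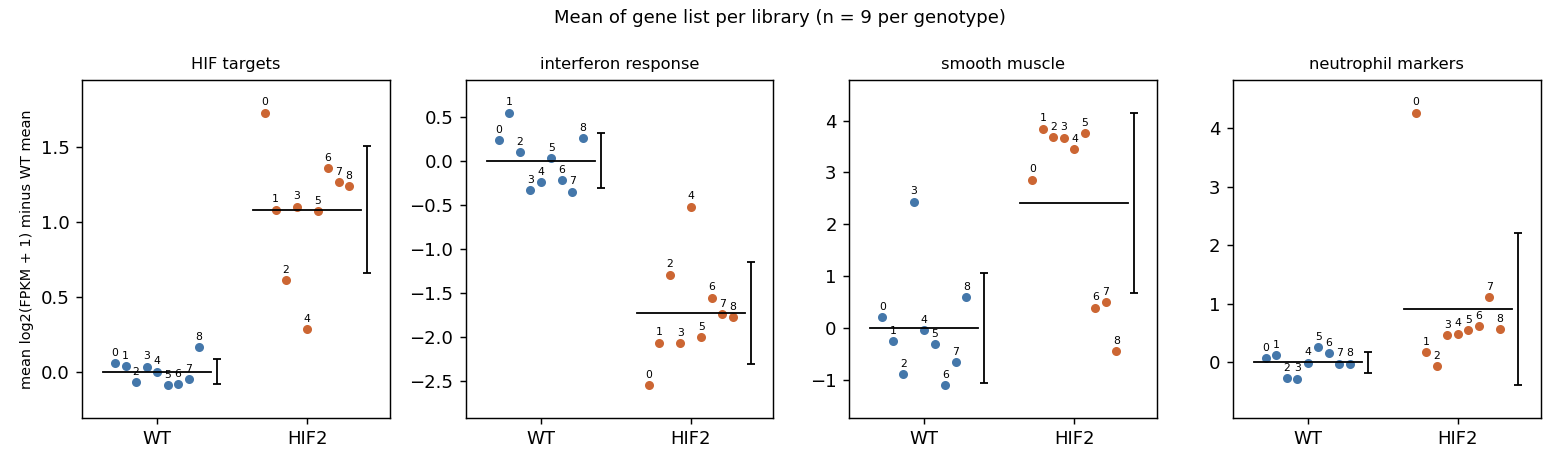
Mean log2(FPKM + 1) of 4 gene lists per library, relative to the WT mean, for HIF target, interferon response, smooth muscle and neutrophil marker genes; points are libraries labelled with their replicate number, lines are group means and bars are SD (n = 9). The 9 HIF2 libraries lie below the WT minimum of -0.35 for interferon genes, and HIF2 replicates 6 to 8 lie inside the WT range for smooth muscle genes.

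Genes of smooth muscle and other stromal cells rose. Of 20 smooth muscle genes, 19 rose and 20 adjusted over the list alone, with a median of 2.60 (camera adjusted p = 1.89e-10, and adjusted p = 0.306 with an estimated correlation). Actg2, enteric smooth muscle actin (chromosome 6, 83512905 to 83536265), was 40.6 ± 90.7 FPKM in WT and 429 ± 348 in HIF2, a log2 change of 3.93 (SE 1.07, adjusted p = 0.0126). Cnn1 rose by 3.54 and Acta2 by 3.45. The smooth muscle mean was not raised in every HIF2 library. Relative to WT it lay between 2.86 and 3.85 in HIF2 replicates 0 to 5, at 0.40, 0.50 and -0.45 in replicates 6, 7 and 8, and at 2.44 in WT replicate 3. In 8 WT libraries without replicate 3 against HIF2 replicates 6 to 8, a subset chosen after the data were seen by this same RNA, 0 of the 20 genes passed and the camera adjusted p was 0.0889.

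Genes of other cell types also rose. Their lists' camera adjusted p, with the smooth muscle mean as a covariate, was 3.02e-07 for fibroblast, 1.16e-05 for macrophage, 0.00604 for endothelial, 0.0237 for enteric neuron and glia and 0.0348 for YAP target genes, with 14 of 29, 9 of 19, 3 of 18, 2 of 11 and 4 of 20 members rising. Fibroblast and matrix genes rose in 23 of 29 and in 24 adjusted over the list alone (median 2.12, camera adjusted p = 4.47e-17, and adjusted p = 0.194 with an estimated correlation), such as Pdgfra by 1.84 and Col6a3 by 2.30. Enteric neuron and glia genes rose in 10 of 11, 11 adjusted over the list alone (camera adjusted p = 5.89e-08, and adjusted p = 0.21 with an estimated correlation), such as Uchl1 by 2.15. Endothelial and lymphatic genes rose in 17 of 18, 18 adjusted over the list alone (camera adjusted p = 3.52e-11, and adjusted p = 0.21 with an estimated correlation), such as Egfl7 by 1.51. In the subset with little smooth muscle RNA, 14 fibroblast genes rose and 1 fell, and 2 enteric neuron and glia genes and 2 endothelial genes rose. The enteric neuron and glia list did not pass there (camera adjusted p = 0.106). Macrophage, monocyte and dendritic cell genes rose in 13 of 19, 15 adjusted over the list alone (median 1.02, camera adjusted p = 2.05e-10, and adjusted p = 0.0761 with an estimated correlation), such as C1qa by 1.75 and Csf1r by 1.61, and 7 rose in that subset. Of 20 YAP target genes, 11 rose, also 11 adjusted over the list alone (camera adjusted p = 1.02e-06, and adjusted p = 0.265 with an estimated correlation), such as Wwtr1 by 2.12, and in that subset the list's adjusted p was 0.146.

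Blood genes rose in 4 of 6, the same number adjusted over the list alone (camera adjusted p = 0.0084, and adjusted p = 0.194 with an estimated correlation), and their mean was 3.38 above WT in HIF2 replicate 0. Only 1 rose with the smooth muscle covariate. Inflammatory mediator genes rose in 6 of 29, also 6 adjusted over the list alone (camera adjusted p = 0.0111, and adjusted p = 0.355 with an estimated correlation), such as Tnf by 1.25. That list call was lost with the filter at 5 FPKM (adjusted p = 0.0595), and 2 members rose with the smooth muscle covariate. The list mean was 1.42 in HIF2 replicate 0 and 0.08 to 0.59 in the other HIF2 libraries, against a WT maximum of 0.40.

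Epithelial genes were lower in several lists. Of 32 absorptive colonocyte genes, 12 fell, 13 adjusted over the list alone (median -0.46, camera adjusted p = 7.93e-05, and adjusted p = 0.246 with an estimated correlation). Of these, 11 fell and 3 rose with the smooth muscle covariate (median -0.31), and 15 fell and 5 rose in HIF2 replicates 6 to 8. The list mean was -1.3 in HIF2 replicate 0 and between -0.61 and -0.23 in the other HIF2 libraries. Car4, a brush border carbonic anhydrase, changed by -1.69 and the butyrate transporter gene Slc5a8 by -1.49. Of 18 goblet cell genes, 9 fell and 2 rose, and adjusted over the list alone 11 and 2 (camera adjusted p = 0.0155, and adjusted p = 0.416 with an estimated correlation). The secretory lineage factor gene Atoh1 changed by -1.33, while Spink4 rose by 0.71, a call lost in the exact rank test, with the replicate block and in HIF2 replicates 0 to 5 (adjusted p = 0.0515, 0.0564 and 0.0751). The goblet call was lost with the smooth muscle mean as a covariate (adjusted p = 0.0669) and in HIF2 replicates 0 to 5 (adjusted p = 0.0667). Genes typical of small intestine or pancreas fell in 10 of 21, 11 adjusted over the list alone (median -1.23, camera adjusted p = 9.49e-08, and adjusted p = 0.0522 with an estimated correlation). Sis, sucrase-isomaltase (chromosome 3, 72888557 to 72967863), was 21.3 ± 7.52 FPKM in WT and 3.85 ± 2.11 in HIF2, a log2 change of -2.26 (SE 0.24, adjusted p = 8.11e-06). The ileal bile acid binding gene Fabp6 changed by -2.86, the peptidase gene Anpep by -2.60 and the Paneth cell defensin gene Defa24 by -2.80, a call lost with the smooth muscle covariate (adjusted p = 0.0557) and in HIF2 replicates 6 to 8 (adjusted p = 0.132). Defa6, another defensin gene, was listed at 0 in each HIF2 library and at a mean of 15.8 ± 16.5 FPKM in WT.

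Lipid synthesis and detoxification genes were also lower. Fatty acid and cholesterol synthesis genes fell in 10 of 26, 14 adjusted over the list alone (camera adjusted p = 1.44e-05, and adjusted p = 0.306 with an estimated correlation), such as Fasn by -0.63. Of these, 3 fell and 1 rose with the smooth muscle covariate (median -0.19 against -0.33), and 5 and 1 in HIF2 replicates 6 to 8 (median -0.13). Xenobiotic detoxification genes fell in 17 of 43 and rose in 3, 21 and 3 adjusted over the list alone (camera adjusted p = 0.00154, and adjusted p = 0.416 with an estimated correlation), such as Cyp3a25 by -1.30. With that covariate 14 fell and 5 rose, and in that subset 20 and 7. Crypt and stem cell genes fell in 6 of 18 and rose in 1, 7 and 1 adjusted over the list alone (camera adjusted p = 0.033, and adjusted p = 0.129 with an estimated correlation), a call lost with the filter at 5 FPKM (adjusted p = 0.181) and in HIF2 replicates 0 to 5 (adjusted p = 0.0885). The gene that rose was the stem cell marker Lgr5, from 2.67 to 16 FPKM, by 1.92, while Sox9 changed by -0.97. Proximal colon genes fell in 2 of 11, 3 adjusted over the list alone (camera adjusted p = 0.0447, and adjusted p = 0.358 with an estimated correlation), a call lost without any 1 of WT replicates 2, 3, 4 or 5 or HIF2 replicates 0, 5, 6 or 7, with adjusted p up to 0.11. It was also lost with array weights, the filter at 5 FPKM and a pseudocount of 0.01 (adjusted p = 0.205, 0.145 and 0.0519), and in HIF2 replicates 0 to 5 (adjusted p = 0.0771).

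The remaining lists had no camera call. By exact permutation of list means, enteroendocrine and tuft cell, stress and Wnt target genes passed (adjusted p = 0.00215, 0.00374 and 0.0346). Their means differed by 0.25, 0.46 and 0.16, and the other lists tested here did not pass. Antimicrobial genes rose in 2 and fell in 6 of 21 (2 and 6 adjusted over the list alone, camera adjusted p = 0.282), and enteroendocrine and tuft cell genes in 5 and 5 of 15 (5 and 5, 0.563). For T and NK cell genes 1 of 6 fell (2 with 1 higher, 0.451), and for B and plasma cell genes 1 of 6 (1, 0.71). MHC class II genes had 0 calls in 7 (0, 0.631). Wnt target genes rose in 3 and fell in 2 of 14 (3 and 2, 0.997), with a median of 0.02 and a mean of 0.16 although camera's direction was down. Cell cycle genes rose in 2 and fell in 1 of 28 (0 and 1, 0.217), and lipid oxidation genes in 4 and 6 of 32 (4 and 6, 0.546). Lipid oxidation genes rose in 11 and fell in 1 with the smooth muscle covariate (adjusted p = 0.0237), and in HIF2 replicates 6 to 8 also in 11 and 1 (adjusted p = 0.0196). Nuclear respiratory chain genes fell in 4 of 30 (3, 0.0964). Leaving out HIF2 replicate 5 gave the cell cycle list an adjusted p of 0.0334, and leaving out HIF2 replicate 6 or 7 gave the respiratory chain list 0.0359 or 0.0164. That list also passed with no filter, TPM scaling and in HIF2 replicates 0 to 5 (adjusted p = 0.0104, 0.0285 and 0.0016). Interstitial cell and adipose genes rose in 1 and fell in 2 of 11 (1 and 2, 0.589), distal colon genes rose in 2 of 6 (2, 0.223), and stress genes in 3 of 17 (3, 0.104). The distal colon list passed with the smooth muscle covariate (adjusted p = 0.0348) and the stress list with the filter at 5 FPKM (adjusted p = 0.0355). Unfolded protein response genes fell in 3 of 20 (3, 0.753). Of 4 tested mast cell and eosinophil genes, 2 rose and 1 fell (3 and 1 adjusted over the list alone), and of 4 sex-linked genes 0 changed (0).

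Of the 37 lists, 10 were called higher and 8 lower with the preset correlation, and 0 in either direction with an estimated correlation. By fry 21 lists passed, and by exact permutation of list means 25. Other splits of the 18 libraries gave up to 21 camera calls at the preset correlation, with a median of 11, so such calls also arose in mixed groups. Of 100 splits, the real one included, 9 gave at least the 18 observed. The number of lists called by camera at that setting was thus not beyond chance. This concerns that count only, and the counts by fry and by list means were not compared over these splits.

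**Figure D3:**
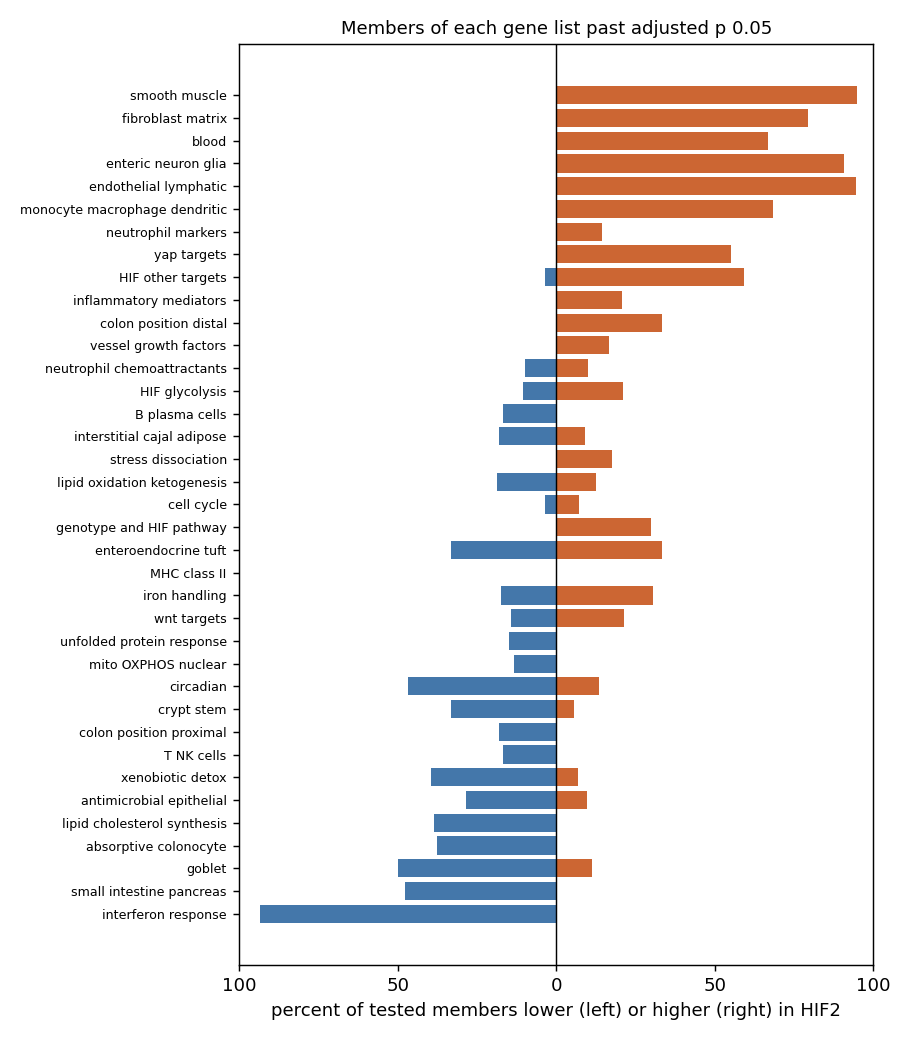
Share of the tested members of each of the 37 gene lists that were lower (left) or higher (right) in HIF2 at a limma adjusted p under 0.05, in percent, with lists ordered by median log2 change. Smooth muscle genes, with 19 of 20 higher, and interferon response genes, with 29 of 31 lower, are at the ends.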

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

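All tests of explanations here were chosen after the results they measure had been seen, apart from the counts over other splits of the libraries. A further comparison of HIF2 replicates 2 and 4 with the other HIF2 libraries was tried and set aside, because it formed groups from the outcome. A test of muscle wall as the whole cause of the higher fibroblast genes was also set aside, because its cutoff was set with the count known.

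A sample far from the others of its group was found in 51 of 336 groups of 9 values, where chance gives about 1 in 20 (5%). That rate does not hold for 12 genes, Cxcl2, Cxcl3, Cxcl5, S100a8, Ngp, Retnlg, Mmp8, Fpr1, Fpr2, Clec4d, Clec4e and Hdc, which were named only because HIF2 replicate 0 lifted their mean to 1 FPKM. Among list means it was 15 of 74 groups, and the lists share genes and libraries. The lists were fixed beforehand, but members such as Cxcl5 and Il1r2 passed the filter only through HIF2 replicate 0. The 5% rate therefore does not hold for lists with such members either. HIF2 replicate 0 accounted for 11 of the list means and 25 of the genes. Relative to the WT mean, its list means were 2.25 for chemoattractants, 4.27 for neutrophil markers, 1.42 for inflammatory mediators, 2.28 for YAP targets, 3.38 for blood, 1.68 for stress genes and 0.94 for vessel growth factors. It was lowest for MHC class II at -1.27, absorptive colonocytes at -1.3, goblet cells at -1.18 and detoxification at -1.23.

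Among genes, HIF2 replicate 0 was the highest HIF2 library for Hif1a at 142 FPKM, Cxcl1 at 37.6, Cxcl2 at 45.4, Cxcl3 at 19.8, Cxcl5 at 81.4, S100a8 at 421, S100a9 at 333 and Retnlg at 54.8. It was also highest for Slpi at 192 FPKM, Il1r2 at 15.5, Ngp at 12, Mmp8 at 11.1, Fpr1 at 8.41, Fpr2 at 8.48, Clec4d at 11.1, Clec4e at 9.92 and Hdc at 10.5. The same held for Nfil3 at 19.5 FPKM, Ret at 8.61, Anpep at 9.69 and Defa24 at 1.1. It was lowest for Steap3 at 1.44 FPKM, Ern2 at 12.6, Atoh1 at 2.37 and Acly at 36.1. HIF2 replicate 4 was highest for Oas2 at 4.62 FPKM.

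Among WT libraries, replicate 3 stood apart with a smooth muscle mean of 2.44 and a goblet mean of -0.61. It was highest for Actg2 at 281 FPKM, Cald1 at 16.6 and S100a9 at 0.891, and lowest for Cd177 at 28.9 and Atoh1 at 28.5. Replicate 8 was highest for macrophage genes at 0.73, stress genes at 0.31 and Hhip at 2.86 FPKM. Replicate 7 was lowest for Lgr5 at 1.5 FPKM and Adm at 2, and replicate 5 was highest for Il1r2 at 0.26 and Clec4e at 0.128.

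Slc11a2 and Egln3 lay inside the WT range in HIF2 replicates 2 and 4, while the HIF target means there, 0.61 and 0.28, were above the WT maximum of 0.16. A swap with a WT library is argued against by 0 WT libraries with Slc11a2 above the HIF2 median of 422.4 FPKM. Less epithelial RNA is argued against by absorptive means of -0.45 and -0.23 relative to WT. Libraries exchangeable with the 9 WT ones are argued against by both of these 2 libraries having interferon means and clock gene differences below the WT range, though replicate 4 was close to that range for interferon. That animals without an active transgene were collected with the HIF2 group cannot be told apart from lower activity, because Epas1 lay inside the WT range in 5 HIF2 libraries, these 2 included, and whether the Epas1 row counts transgene RNA is not given in the sources used here.

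Smooth muscle, nerve and stromal RNA was higher in HIF2. An effect of similar size in every HIF2 library is argued against by 3 HIF2 libraries with a smooth muscle mean inside the WT range, at 0.50 or less where the other 6 were at 2.86 or more. A smaller effect in those 3 is not excluded. For more muscle wall in the tissue taken, the median pairwise correlation among smooth muscle genes over the WT libraries was computed. It was 0.93, and 0.78 without WT replicate 3, against at most 0.26 in 1000 random lists. Markers of 1 cell type vary together whatever raised them in HIF2, so this cannot tell more muscle wall from a response of stroma. Of 29 fibroblast genes, 14 passed with the smooth muscle mean as a covariate (median 0.943), against 23 without it, which is given as a value and not as a verdict. The labels say nothing of how the pieces were cut. HIF2 replicates 6, 7 and 8 had the highest Slc11a2, at 2008, 2101 and 1525 FPKM, with smooth muscle means of 0.40, 0.50 and -0.45. Replicates 2 and 4, with Slc11a2 at 16.5 and 18.2 FPKM, had means of 3.69 and 3.44, and WT replicate 3 had 2.44. These values argue against a smooth muscle rise in step with Slc11a2. More muscle wall, and a response of stroma to the genotype in part of the animals but not in step with Slc11a2, both stay open.

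Interferon response genes were lower in HIF2. Dilution by muscle RNA as the whole cause is argued against by 27 of 31 genes passing with the smooth muscle mean as a covariate (median -1.47). Unequal sex is argued against by sex-linked genes, of which 0 of 4 changed, with log2 changes between -0.11 and 0.18. With Xist and Ddx3y as covariates 29 interferon genes passed (median -1.55). That balance left this covariate test little room to give another result. HIF target activity of each library as the whole cause stays open, because the answer depends on the list used to measure it. In HIF2 replicates 2 and 4, where interferon means lay below the WT range, other lists did not lie above that range. Their means were 0.24 and -0.22 for the HIF pathway (WT maximum 0.32) and 0.034 and 0.039 for iron handling (WT maximum 0.10). For glycolysis they were -0.26 and -0.13 (WT minimum -0.10). A total of 0 HIF2 libraries had HIF target means inside the WT range with interferon means below it. The libraries, however, formed 2 clusters by Slc11a2. Within the 7 with Slc11a2 above WT, r was -0.43 (permutation p = 0.319) and rho 0.11 (permutation p = 0.839), adjusted 0.319 and 0.839 over 4 relations. Without the 2 farthest libraries r turned to 1. These 7 also mix replicates 6 to 8, which lay apart on the second principal component, with replicates 0, 1, 3 and 5. Their r therefore decides nothing either. Within WT r was 0.43 (permutation p = 0.251, adjusted 0.319) and rho 0.47 (permutation p = 0.215, adjusted 0.286). The other 2 relations, over all 9 HIF2 libraries and over replicates 0 to 5, were negative but mixed both clusters, so no r is given. The adjusted permutation p of these 2 relations was 0.00846 and 0.00572 for r, and 0.286 and 0.0113 for rho. A difference in housing, microbes or collection between the groups was not tested, and the labels give none of these.

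Chance can be excluded for the number of changed genes, since 1 of 100 splits, the real one, gave as many as 3088, and the highest other gave 1934. The same held for 1531 higher and 1557 lower, each with 1 of 100 splits and 1115 at most in another. The highest other split kept 8 libraries of 1 genotype on one side and put the 7 libraries rich in smooth muscle RNA together. For the count of 18 gene lists called by camera at the preset correlation, chance cannot be excluded. Of 100 splits, 9 gave as many, and the highest other gave 21.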

How the results depend on the processing

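The subsets of libraries named here, 8 WT against HIF2 replicates 6 to 8 and 9 WT against HIF2 replicates 0 to 5, were chosen after seeing the data. These subsets and the smooth muscle covariate left sex-linked genes unbalanced, with medians of -2.17, 1.37 and -2.13 over 4 genes. Values under them cannot be assigned to muscle RNA alone. Over 182 results and 5410 values under alternatives, planned ones kept direction and side of the threshold in 1990, with 62 weaker, 20 stronger, 12 reversed and 6 counts moved. Leaving out single libraries gave 2893 kept, 70 weaker, 12 stronger and 13 reversed, and the added subsets 271 kept, 39 weaker, 6 stronger, 14 reversed and 2 moved. Genes higher numbered 640 with a filter at 5 FPKM, where 9287 genes were tested, and 2407 with no filter, where 22774 were tested. With the smooth muscle mean as a covariate 943 were higher and 1000 lower, and 1281 of the 3088 main calls were kept. By at least 2-fold, 268 were higher with the filter at 5, 297 with that covariate and 371 in the subset of HIF2 replicates 6 to 8, where 315 were lower. Without single libraries, higher ranged from 1333 to 1653, lower from 1343 to 1662, 2-fold higher from 609 to 769 and 2-fold lower from 168 to 242, lists higher from 9 to 12 and lower from 7 to 8. With the replicate number as a block, 1355 were higher and 1345 lower, and 2577 main calls were kept. The numbers did not pair the libraries, with correlations of same-numbered deviations from -0.03 to 0.11, over 0.1 in 1 of 9 pairs, and 0 WT libraries correlating best with their own number.

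Among named genes and lists, each reversal was of a result not past its threshold in the main test, and the cause was not tested. Over all genes 1 of the 3088 main calls, Des, turned past the threshold with the smooth muscle covariate (3.22 to -0.54, adjusted p = 0.0321), and Des is itself in the list that makes this covariate. Interstitial cell genes alone passed after turning (adjusted p = 0.0385 with the smooth muscle covariate and 0.0439 in HIF2 replicates 6 to 8). Ly6c2 was -0.16 with a pseudocount of 0.01 and -0.024 with array weights. List medians, where camera's direction turned, were -0.25 for antimicrobial and -0.025 for unfolded protein response genes with the filter at 5, -0.11 for enteroendocrine and 0.10 for Wnt target genes with no filter, and 0.017 for unfolded protein response genes with quantile normalization. With the smooth muscle covariate they were 0.13 for B cells, 0.15 for respiratory chain, -0.85 for interstitial cells and 0.088 for unfolded protein response, and Cd177 was 0.59. Without single libraries, Wnt targets ranged from -0.091 to 0.043, MHC class II from -0.12 to 0.22, unfolded protein response from -0.053 to 0.034, Cd177 from -0.22 to 0.009 and Cxcl2 from -0.08 to 0.61. In HIF2 replicates 6 to 8 they were 0.004 for chemoattractants, 0.089 for B cells, 0.071 for Wnt targets, 0.16 for respiratory chain, -0.82 for interstitial cells, 0.13 for unfolded protein response, 0.38 for Cd177, -0.044 for Cxcl2 and -0.16 for Cxcl5. In HIF2 replicates 0 to 5 they were -0.23 for T and NK cells, -0.10 for Wnt targets, -0.084 for lipid oxidation, 0.068 for Arnt and 0.12 for Ccl9. Epas1 was 0.47 with an adjusted p of 0.0415 in HIF2 replicates 6 to 8. Gene lists and 2-fold counts have no value under the rank test. Smooth muscle genes under their own covariate were not counted as kept or changed, because they make that covariate. There 0 of 20 rose and 2 fell (median -0.007). Absolute depth is unknown, so the counting error of low genes is not covered.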

Other observations

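The test of the clock genes here was chosen after their values had been seen. Of 15 tested circadian clock genes, 7 fell and 2 rose, and the same numbers adjusted over the list alone (camera adjusted p = 0.0964, and adjusted p = 0.355 with an estimated correlation). The mean of the list differed by -0.30 (exact permutation adjusted p = 0.0022). Camera passed with the smooth muscle covariate (adjusted p = 0.0445). Dbp, a clock output factor gene, was 18.2 FPKM in WT and 4.76 in HIF2, a log2 change of -1.87 (SE 0.23, adjusted p = 2.69e-05), and Ciart changed by -1.95 (SE 0.18, adjusted p = 2.54e-06). Npas2 rose by 1.23 and Nfil3 by 1.39. Tef, Nr1d1, Nr1d2 and Per3, chosen after their values were seen, changed by -0.83, -0.78, -0.66 and -0.93.

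A hypothesis is that the tissue of the groups was collected at another phase of the day. The mean of 9 genes, Dbp, Tef, Hlf, Ciart, Nr1d1, Nr1d2 and Per1 to Per3, changed by -0.82 (exact permutation p = 8.23e-05), and that of 5 genes in the opposite phase, Arntl, Npas2, Clock, Nfil3 and Cry1, by 0.61 (exact permutation p = 4.11e-05, the smallest possible). Their difference changed by -1.43, and it lay below the WT range in 9 of 9 HIF2 libraries, including replicate 2 at -1.81 and replicate 4 at -1.34. This is consistent with a shift in phase, but collection times are not given in the sources used here, and an effect of the genotype on the clock was not separated from it. Arntl, Clock, Per1 and Cry1, chosen after their values were seen, did not pass by themselves (adjusted p = 0.28, 0.341, 0.653 and 0.381). Clock, at -0.13, and Hlf, from 0.451 to 1.03 FPKM, went against their sets.

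Tuft cell genes Trpm5 and Avil changed by -1.10 and -0.67, while the secretory granule genes Scg2 and Scg5 rose by 1.95 and 0.94, within the list of enteroendocrine and tuft cell genes. Scg2 was 6.26 to 16.2 FPKM in HIF2 replicates 0 to 5 and 2.21 to 4.53 in replicates 6 to 8, and the enteric neuron gene Uchl1 was 5.56 to 16.9 and 2.29 to 5.1 FPKM in the same libraries.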
